A study of Homo sapiens with 12 samples.

How the data were processed

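RNA abundance was measured by sequencing in 4 established cell lines of diffuse large B-cell lymphoma (DLBCL), U2932, SUDHL-4, TMD8 and WSU-DLCL2. Per the labels' protocols, each line was cultured for 18 hours with the solvent DMSO, with lenalidomide or with avadomide, also called CC-122, before RNA was taken. This gave 12 libraries, 1 for each line and treatment, and 4 for each treatment. Each library's treatment and line came from the labels. Doses are not given in the sources used here, so the doses of the 2 compounds are not known to match. With 1 library for each line and treatment there is no replicate within a line, and the labels do not say whether libraries share a batch. The p-values rest on how evenly a change appeared over these 4 lines, a spread that may be partly technical.

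The authors deposited one table of log2 values per gene and library, running from -2.41 to 20.1. STAR, Salmon and genome build hg38 are named in the submitters' processing notes, without versions. MACS is named there too and does not apply to expression values. The normalization and the exact transform behind the deposited log2 values are not given in the sources used here. The values have no whole-number steps, 17112 genes are listed at exactly 0 in all 12 libraries, and the spread within a line, a median SD of 0.381 for genes with means from 0 to 1, shrinks below that to 0.0155 for means from -3 to -2. This is the pattern of a regularized log of normalized read counts, on which changes of genes with low values are understated. No read counts could be recovered, so sequencing depth is unknown and no counting interval is given. The values, made linear, summed and divided by 10 to the power of 6, came to between 85.8 and 92.4 per library, which is a scale and not a depth. Precision among tested genes depended on level. The median residual SD was 0.297 for genes with mean log2 values from 1 to 5, 0.142 from 5 to 10 and 0.0683 from 10 to 15.

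The table held 58684 entries. Of these, 28 had a gene symbol turned into a calendar date by spreadsheet software and were left out. No columns without a sample were present, and no pair of libraries had identical values. Genes with a log2 value of at least 1 in at least 4 libraries were tested, which left 22528 genes, 17356 of them with a gene symbol and 5172 with a clone-based name.

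Tests used limma 3.58.1 in R 4.3.3, with an intensity trend in the variance prior, on the log2 values as deposited. One model with treatment and cell line as factors was fitted to all 12 libraries, with 6 residual and 9.62 total degrees of freedom. The 3 contrasts were avadomide against DMSO, lenalidomide against DMSO and avadomide against lenalidomide. The threshold was a Benjamini-Hochberg adjusted p of 0.05 with no minimum fold, and all tests were two-sided. Log2 fold changes are given with the standard error (SE) of the fit over 4 lines. This fit pools the spread of all 12 libraries, so a gene has the same SE in all 3 comparisons. A comparison with a smaller spread of its own is thus tested against the pooled one. The plan made before the data were examined assumed linear or count values, with a pseudocount or a count model. As the deposited values were already on a log2 scale, neither was used.

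Cell line is the pairing factor, since libraries with the same number in the labelled design come from the same line. As a check, deviations from the treatment means correlated at 0.918 to 0.977 between libraries of the same line and at -0.589 to 0.199 between lines. Correlations of the values themselves were 0.988 to 0.998 within a line and 0.890 to 0.963 between lines.

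Before the data were examined, 20 gene lists with 372 genes were fixed. They covered the cereblon ligase and its substrates, the type I interferon response, MHC class I and class II presentation, NF-kB targets, MYC and ribosome biogenesis, the cell cycle, apoptosis, p53 targets, corepressor complexes, B cell identity, plasma cell differentiation, pre-B cell genes, immune ligands, the unfolded protein and integrated stress response, cholesterol synthesis and mitochondrially encoded genes. Markers of T and NK cells, of myeloid cells and of stromal and epithelial cells stood for cells that might be mixed in. Some genes are in more than one list. Each list was tested with camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, adjusted over the 20 lists of a comparison. No list was chosen on these samples. With 1 library per line and treatment there is no test within a line. There a list's median was set among 10000 random lists of the same size matched on mean expression, as a description of that library. An exact two-sided sign-flip test over 4 lines cannot give a p below 0.125.

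Genes are named by a rule fixed before the data were examined. It takes CRBN, IKZF1, IKZF3, IRF4, MYC and IRF7. It adds, for each compound against DMSO, the 10 largest rises and the 10 largest falls among called genes that moved the same way in all 4 lines and had a mean of at least 1 ppm of the summed linear values. For avadomide against lenalidomide it takes 5 and 5. From each list it takes up to 4 members with the smallest p under avadomide. Clone-named loci were passed over. Other list members are named as examples, chosen after their values were seen. Gene positions are from GENCODE release 29 on GRCh38, and whether the authors counted by strand is not given in the sources used here.

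The agreement of the 2 compounds was measured as a correlation and a covariance of log2 fold changes across genes. Both use the same DMSO libraries, so 100 simulations of unchanged groups against the same controls gave the chance values, and the controls were split by line in 6 ways. On data simulated from these libraries with 200 genes changed, the fit for avadomide against DMSO recovered 71% of changes of log2 1 and 46% of changes of log2 0.5. For lenalidomide against DMSO the shares were 67% and 45%, and for avadomide against lenalidomide 79% and 54%. False calls made up 4.10%, 4.27% and 4.32% of calls. The simulation drew noise independently for each gene and gave every line the same change, so these shares need not hold for the real libraries.

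Alternatives planned before the data were examined were a fit without the cell line, leaving out each line in turn, no filter, a stricter filter of at least 5 in at least 4 libraries (15191 genes), quantile normalization, a fit to only the 8 libraries compared, camera with an estimated correlation, split controls, and genes of at least 5 ppm. Other pseudocounts and count-based tools were planned too and not run, because the deposited values are log2. A correction for GC content and transcript length was added after the data were seen. For each library, splines with 4 degrees of freedom were fitted to its deviation from the mean of its line. The fit used genes with a mean log2 value of at least 5 and had an intercept, so it also recentred each library. It covered 99.6% of the symbol-named genes and 76.7% of all tested genes, so it speaks for symbol-named genes only, and the same genes were also fitted without it. Families of genes grouped by symbol were added after the data were seen as well.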

Results

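The transcriptomes of 4 DLBCL cell lines were measured after 18 hours with DMSO, lenalidomide or avadomide, in 12 libraries. Lenalidomide and avadomide are cereblon modulators. They bind cereblon (CRBN), the substrate receptor of a CUL4-DDB1 ubiquitin ligase, and direct it to the lymphoid transcription factors Ikaros (IKZF1) and Aiolos (IKZF3), which are then degraded as proteins. Both carry the glutarimide ring that binds cereblon. Lenalidomide joins it to an amino-substituted isoindolinone, and avadomide to a quinazolinone with an amino and a methyl group. The study's title concerns the protein partners of Ikaros and Aiolos and the pairing of cereblon modulators with histone deacetylase inhibitors. The RNA part asks what each compound does to transcript levels and, through the lines, how general that is. U2932 and TMD8 are lines of the activated B-cell type and SUDHL-4 and WSU-DLCL2 of the germinal-centre type, as background. Between 13865 and 15294 genes per library had a log2 value of at least 5, and mitochondrially encoded genes made up 3.95% to 5.27% of the summed linear values.

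The drug targets and study genes were read first. IKZF1 RNA (chromosome 7, 50304068 to 50405101) rose under avadomide by 0.72 ± 0.09 (log2, SE, n = 4 lines; limma adjusted p = 0.000780), in 4 of 4 lines. IKZF3 (chromosome 17, 39757715 to 39864188) rose by 0.38 ± 0.07 (adjusted p = 0.00646), also in 4 of 4. MYC (chromosome 8, 127735434 to 127741434) fell by 0.37 ± 0.05 (adjusted p = 0.00165) in all 4 lines. IRF7, a transcription factor that drives interferon genes (chromosome 11, 612553 to 615999), rose by 1.90 ± 0.40 (adjusted p = 0.00850), with values of 2.37 in U2932, 2.42 in TMD8, 2.88 in WSU-DLCL2 and -0.058 in SUDHL-4. The IRF7 call was lost without U2932 (adjusted p = 0.0598) and without WSU-DLCL2 (adjusted p = 0.0606). CRBN itself (chromosome 3, 3144628 to 3179727) had a log2 fold change of 0.022 with a 95% interval from -0.10 to 0.14 under avadomide (adjusted p = 0.815). IRF4, a regulator of B-cell and plasma-cell fate (chromosome 6, 391739 to 411447), had a mean change of -0.073 ± 0.33 (adjusted p = 0.90), made of -0.68 in U2932, 0.018 in SUDHL-4, -1.14 in TMD8 and 1.51 in WSU-DLCL2. Under lenalidomide none of these 6 genes passed the threshold in limma. IKZF1 stood at 0.30 ± 0.09 (adjusted p = 0.173), IKZF3 at 0.18 ± 0.07 (adjusted p = 0.358), MYC at -0.13 ± 0.05 (adjusted p = 0.341) and IRF7 at 0.38 ± 0.40 (adjusted p = 0.749). These SEs include the spread of the avadomide libraries, so a missed threshold here does not show that lenalidomide had no effect. Under lenalidomide the IRF7 changes were 0.43 in U2932, -0.020 in SUDHL-4, 0.76 in TMD8 and 0.34 in WSU-DLCL2.

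**Figure D1:**
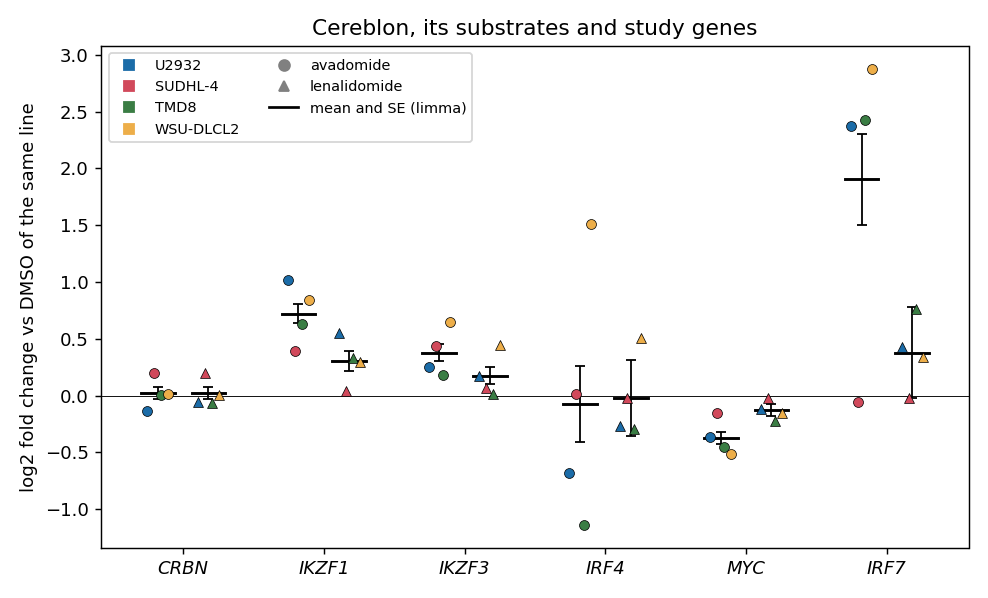
Log2 fold change of 6 genes against the DMSO library of the same line (y axis), for avadomide (circles) and lenalidomide (triangles). Each point is 1 line, the bar is the mean over 4 lines and the whisker its SE from limma; IKZF1, IKZF3, MYC and IRF7 passed the threshold under avadomide, and the IRF4 points run from -1.14 in TMD8 to 1.51 in WSU-DLCL2.

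Avadomide against DMSO asked which transcripts the newer compound moves. The largest rises by the naming rule were those of genes induced by type I interferon. IFIT1, an antiviral RNA-binding protein (chromosome 10, 89392546 to 89406486), rose by 5.17 ± 0.57 (log2, SE, n = 4), which is 36.1-fold on the scale of the deposited values, with a limma adjusted p of 0.000567. XAF1, IFI44L, IFIT3, IFI44 and IFI6 rose by 5.06, 4.86, 4.85, 4.27 and 3.98. LGALS3BP, also in the interferon list, rose by 3.89 ± 0.59. The other rises among the 10 largest by that rule were CC2D2A, a ciliary protein (3.97 ± 0.34), the protease inhibitor A2M (3.82 ± 0.77) and CHI3L1 (3.74 ± 1.04). Among falls, ATP13A4, a cation-transporting ATPase, changed by -1.95 ± 0.19 and GDF7, a growth factor of the BMP family, by -1.85 ± 0.33. The transglutaminase TGM2 changed by -1.80 ± 0.27, the adhesion receptors ADGRG5 and CELSR2 by -1.77 ± 0.51 and -1.74 ± 0.14, and REEP2, GREB1, FDXACB1, CCDC102A and ABCA2 by -1.62, -1.42, -1.38, -1.22 and -1.20. In all, 5582 of 22528 genes passed the threshold, 3068 higher and 2514 lower, and 5189 of them moved the same way in 4 of 4 lines. Most changes were small, with a median size of 0.32 among called genes. At least 2-fold changes numbered 651 higher and 53 lower.

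The count of avadomide calls was 3315 without U2932 and 2666 without WSU-DLCL2, 1376 in a fit to only the 8 libraries compared and 0 without the cell line as block (514 genes at an unadjusted p under 0.05 in limma). The split of higher against lower genes moved with scaling, to 2521 against 3685 after quantile normalization. After removal of the GC and length trend it was 1930 against 3401, where the same genes without the removal gave 2627 against 2449. The removal also recentred each library, so this shift need not come from GC content and length alone. Calls were lost for A2M without U2932 (3.07; adjusted p = 0.0506), for CHI3L1 without U2932 (3.22; 0.142) or TMD8 (2.26; 0.0858), and for ADGRG5 without U2932 (-2.08; 0.0614) or SUDHL-4 (-1.92; 0.0807). Fold changes followed GC content across genes in each line, with Spearman correlations of -0.105 in U2932, -0.572 in SUDHL-4, -0.0996 in TMD8 and -0.327 in WSU-DLCL2. Genes are not independent replicates, so these carry no p.

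Of the 47 measured genes of the interferon list, 43 rose under avadomide and 0 fell (47 rose adjusted over the list alone), with a median log2 fold change of 1.98. The list stood above other genes by camera (adjusted p = 3.18e-20), though with an estimated correlation between genes the adjusted p was 0.358. It passed by fry (adjusted p = 0.00867). Besides the genes above, PLSCR1 rose by 1.35 ± 0.13, the antiviral GTPase MX1 by 3.70, RSAD2 by 3.68 and the chemokine CXCL10 by 3.25. In single lines the list median was 2.30 in U2932, 1.99 in TMD8 and 2.59 in WSU-DLCL2, against 0.337 in SUDHL-4. At least 2-fold rises were seen for 42, 39 and 44 of the 47 genes in those lines and for 10 in SUDHL-4. The difference between lines was not tested, with 1 library each. All 4 medians lay above the random lists matched on expression. Without U2932 or without WSU-DLCL2, 29 of the 47 genes were called.

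**Figure D2:**
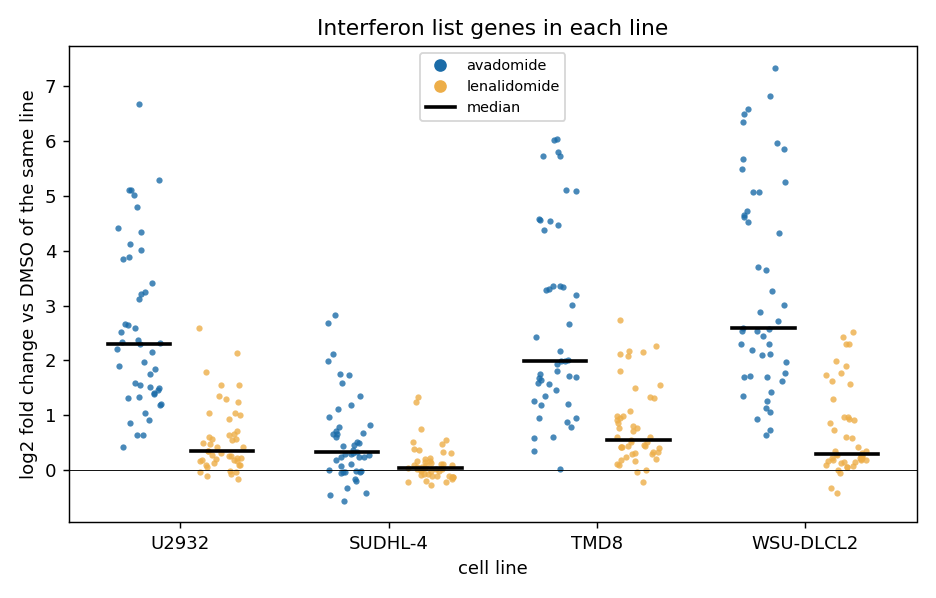
Log2 fold change of each of the 47 interferon list genes (points, spread sideways for legibility) against DMSO of the same line, in 4 lines, for avadomide (blue) and lenalidomide (yellow). Black bars are medians; under avadomide they are 2.30, 0.337, 1.99 and 2.59 from left to right, and under lenalidomide 0.348, 0.0334, 0.543 and 0.295.

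Some antigen presentation and immune signalling genes were higher, with the MHC class I and NF-kB lists past the threshold by camera and neither with an estimated correlation (adjusted p = 0.358 and 0.610). By fry the MHC class I and immune ligand lists passed (adjusted p = 0.0366 and 0.0177) and the NF-kB list did not (0.169). Of 15 MHC class I genes, 9 rose and 0 fell (10 rose and 1 fell adjusted over the list alone), among them HLA-B (0.50 ± 0.12), the immunoproteasome subunit PSMB9 (0.37 ± 0.08) and the peptidase ERAP1 (0.21 ± 0.05). The list median was 0.268, with a camera adjusted p of 0.00165, or an adjusted p of 0.358 with an estimated correlation. HLA genes are near-identical in parts and polymorphic, so their values are uncertain. Of 14 MHC class II genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone), namely the peptide loaders HLA-DMB (0.70 ± 0.08) and HLA-DMA (0.44 ± 0.12); HLA-DRA stood at 0.34 ± 0.12 and HLA-DOA at 0.34 ± 0.12 without passing, and the list missed the threshold (camera adjusted p = 0.0590). Without SUDHL-4 the MHC class II list passed (0.00455), with HLA-DRA and HLA-DOA called (0.0323 and 0.0333), as it did without U2932 (0.0452), while it stood at a median of 0.097 without TMD8 (0.375) and missed without WSU-DLCL2 (0.0675). Of 24 NF-kB targets, 6 rose and 0 fell (6 and 0 adjusted over the list alone), including TNF (0.78 ± 0.10), the apoptosis inhibitor BIRC3 (0.72 ± 0.10), CD40 (0.68 ± 0.15) and the adhesion molecule ICAM1 (0.54 ± 0.11). The NF-kB list had a camera adjusted p of 0.0350 (an adjusted p of 0.610 with an estimated correlation), and 0.631 without WSU-DLCL2, where its median was 0.833 against -0.268 in TMD8. Without WSU-DLCL2, 4 of its genes rose and 4 fell, and without U2932, 4 rose and 0 fell. Of 19 immune ligands, 8 rose and 2 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.0590). The chemokines CXCL9 and CXCL11 rose by 3.0 ± 0.59 and 1.29 ± 0.23 and the phagocytosis inhibitor CD47 by 0.28 ± 0.04, while ULBP3, a ligand of the NK cell receptor NKG2D, changed by -0.62 ± 0.12. Without U2932, 1 MHC class I and 1 class II gene were called, without WSU-DLCL2, 2 and 1, and without SUDHL-4, 7 class II genes; 5 immune ligands rose and 1 fell without U2932 or TMD8, and the immune ligand list passed without U2932 (0.0364) or SUDHL-4 (0.0307). Without U2932 or WSU-DLCL2 the calls of HLA-B, ERAP1 and HLA-DMA were lost, with adjusted p of up to 0.0945; PSMB9 was lost without TMD8 (0.0563; 4 class I genes left) and without WSU-DLCL2 (0.0650), and CD40 without U2932 (0.0572).

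Some genes of growth were lower. Of 23 genes of the MYC and ribosome biogenesis list, 0 rose and 16 fell (21 fell adjusted over the list alone), with a median of -0.214 and a camera adjusted p of 1.97e-11, or an adjusted p of 0.358 with an estimated correlation. CAD, which starts pyrimidine synthesis, changed by -0.39 ± 0.04, and the nucleolar factors NOP16, MYBBP1A and NOP2 by -0.34 ± 0.04, -0.30 ± 0.04 and -0.22 ± 0.03. In the cell cycle list, 14 of 30 genes fell and 3 rose (15 and 3 adjusted over the list alone; median -0.120; camera adjusted p = 0.00186, and adjusted p = 0.358 with an estimated correlation). The cell cycle list missed by fry (adjusted p = 0.0576), and the MYC and ribosome list passed (0.00565). The regulator of S phase entry E2F1 changed by -0.44 ± 0.07, cyclin E1 (CCNE1) by -0.33 ± 0.06 and the replication helicase subunit MCM7 by -0.29 ± 0.04. The genes that rose were the inhibitors of cyclin-dependent kinases CDKN1A (1.19 ± 0.25) and CDKN1B (0.50 ± 0.04) and cyclin D3 (CCND3, 0.22). In the cell cycle list 8 genes fell without U2932, 6 without TMD8 and 3 without WSU-DLCL2.

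Apoptosis regulators moved both ways, 8 of 23 up and 2 down (9 and 3 adjusted over the list alone; camera adjusted p = 0.0590). The pro-apoptotic BMF and PMAIP1 rose by 0.87 ± 0.13 and 0.42 ± 0.05, caspase 8 (CASP8) by 0.25 ± 0.04 and the caspase inhibitor XIAP by 0.36 ± 0.03. Of 17 p53 targets, 3 rose and 3 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.763), with TP53INP1 at 0.67 ± 0.10, FDXR at -0.28 ± 0.05 and the repair factor XPC at -0.17 ± 0.04. In the corepressor list, 2 of 26 rose and 7 fell (2 and 7 adjusted over the list alone; camera adjusted p = 0.0800). The apoptosis list passed as higher by fry (adjusted p = 0.00677) and the corepressor list as lower (0.00385). TBL1XR1 and RCOR1 rose by 0.56 ± 0.06 and 0.29 ± 0.05, and the deacetylase HDAC3 and the NuRD subunit MTA1 changed by -0.21 ± 0.03 and -0.19 ± 0.03. Among 14 cereblon ligase and substrate genes, 8 rose and 3 fell (8 and 3 adjusted over the list alone; median 0.146; camera adjusted p = 0.0252, and adjusted p = 0.358 with an estimated correlation). Helios (IKZF2) rose by 0.89 ± 0.07, the ligase scaffold CUL4B by 0.43 ± 0.04 and ZFP91 by 0.27 ± 0.03, while DDB1, CUL4A and GSPT1 changed by -0.15, -0.14 and -0.15. This list call ended without SUDHL-4 (camera adjusted p = 0.0836), and its median was -0.00837 after the GC and length trend was removed (camera adjusted p = 0.204). The apoptosis list passed without U2932 (0.0178) or SUDHL-4 (0.0423), and 5 of its genes rose and 1 fell without WSU-DLCL2. In the corepressor list 3 genes fell without U2932 and 4 without WSU-DLCL2, in the p53 list 1 without U2932 and 2 without WSU-DLCL2, and in the cereblon list 1 without TMD8 and 0 without WSU-DLCL2, where 5 rose. The call of XPC was lost without U2932 (adjusted p = 0.0654) and without WSU-DLCL2 (0.0680).

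Of 25 B cell identity genes, 1 rose and 9 fell (1 and 9 adjusted over the list alone; camera adjusted p = 0.0611). Tested with fry, this list passed as lower (adjusted p = 0.0152). The adaptor BLNK changed by -0.31 ± 0.07, the receptor CD22 by -0.28 ± 0.07, the coactivator POU2AF1 by -0.24 ± 0.06 and the transcription factor SPIB by -0.50, and the kinase SYK rose by 0.20 ± 0.05. Of 13 plasma cell genes, XBP1, a transcription factor of secretory cells, rose by 0.80 ± 0.05 (adjusted p = 0.000161) and the folding factor FKBP11 changed by -0.25 ± 0.06 (1 and 1 adjusted over the list alone). SDC1 at -0.24 ± 0.16 and JCHAIN at 0.19 ± 0.14 did not pass, and the list had a median of -0.0181, a mean of 0.0641 and a camera adjusted p of 0.957. In the pre-B list 2 of 7 genes rose (2 adjusted over the list alone; camera adjusted p = 0.0994), the stem cell antigen CD34 by 3.41 ± 0.38, from a low mean log2 value of 2.08 to 5.49, and VPREB1, part of the surrogate light chain, by 1.65 ± 0.36; DNTT stood at 0.42 ± 0.16 and SOX4 at 0.11 ± 0.07. Of 14 stress response genes, 4 rose and 5 fell (4 and 5 adjusted over the list alone; median 0.000208, mean -0.000841; camera adjusted p = 0.759). The chaperone cofactor DNAJB9 rose by 0.52 ± 0.05, and asparagine synthetase (ASNS), TRIB3 and ATF4, of the amino acid response, changed by -0.47 ± 0.08, -0.30 ± 0.04 and -0.19 ± 0.04. Of 15 cholesterol synthesis genes, SC5D (0.40 ± 0.05) and IDI1 (0.22 ± 0.07) rose (1 adjusted over the list alone; camera adjusted p = 0.558), with SQLE at 0.12 ± 0.05 and INSIG1 at 0.17 ± 0.08. The B cell list passed without TMD8 (0.0148), though 2 of its genes fell without U2932, 4 without SUDHL-4, 4 without TMD8 and 1 without WSU-DLCL2. The plasma cell median was 0.16 without TMD8, where JCHAIN was called (0.43; adjusted p = 0.00229), SDC1 was called without WSU-DLCL2 (-0.47; 0.0414) and INSIG1 without U2932 (0.28; 0.0152). Of the stress genes 2 rose and 3 fell without WSU-DLCL2 and 3 fell without SUDHL-4, and of the cholesterol genes 3 fell without TMD8. Calls of SYK, CD22, POU2AF1, BLNK, FKBP11, VPREB1 and IDI1 were lost without WSU-DLCL2 (adjusted p from 0.0688 to 0.160), those of SYK, CD22 and VPREB1 without U2932 (0.0859, 0.0927 and 0.0513), those of SYK, CD22, POU2AF1, FKBP11 and IDI1 without TMD8 (from 0.0542 to 0.139), and those of FKBP11 and IDI1 without SUDHL-4 (0.0506 and 0.171).

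Some markers of other cell types were higher with avadomide in these cultured lines. Of 6 measured T and NK cell markers, CD4 rose by 1.75 ± 0.33 and NKG7, a granule protein, by 2.59 ± 0.55 (3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.124), while TRAC stood at 0.52 ± 0.19 and PRF1 at -0.48 ± 0.18. Of 6 myeloid markers, lysozyme (LYZ, 1.64 ± 0.46), FCN1 (0.91 ± 0.27) and CD68 (0.67 ± 0.17) rose and CD14 stood at 0.21 ± 0.15 (3 adjusted over the list alone; camera adjusted p = 0.0611, and 0.0205 without SUDHL-4). Of 8 stromal and epithelial markers, the endothelial adhesion molecule PECAM1 (1.92 ± 0.26) and collagen COL1A1 (1.27 ± 0.29) rose, decorin (DCN) changed by -0.35 ± 0.07 and PDGFRB stood at 0.62 ± 0.26 (2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.456). Tested with fry, the T and NK list and the myeloid list passed as higher (adjusted p = 0.0366 and 0.0205). The stromal and epithelial list missed by fry (adjusted p = 0.0827). Mean log2 values in DMSO were low for LYZ (0.70) and NKG7 (0.96). Of 13 mitochondrially encoded genes, 4 fell and 0 rose (6 fell adjusted over the list alone; median -0.0975; camera adjusted p = 0.00186, and adjusted p = 0.358 with an estimated correlation), namely MT-ATP8 (-0.17 ± 0.04), MT-CYB (-0.14 ± 0.04), MT-CO3 (-0.13 ± 0.03) and MT-CO2 (-0.13). TRAC was called without WSU-DLCL2 (0.77; adjusted p = 0.0272). Without WSU-DLCL2 the calls of NKG7, CD68, LYZ, FCN1, COL1A1 and the 4 mitochondrial genes were lost (adjusted p from 0.0546 to 0.237). Without U2932 those of CD68, LYZ, FCN1 and COL1A1 were lost (0.0587 to 0.142), without TMD8 those of LYZ, COL1A1 and the 4 mitochondrial genes (0.0570 to 0.116), and without SUDHL-4 those of CD68, MT-ATP8, MT-CYB and MT-CO2 (0.0595 to 0.132), and those of MT-CYB and MT-CO2 after quantile normalization too.

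**Figure D3:**
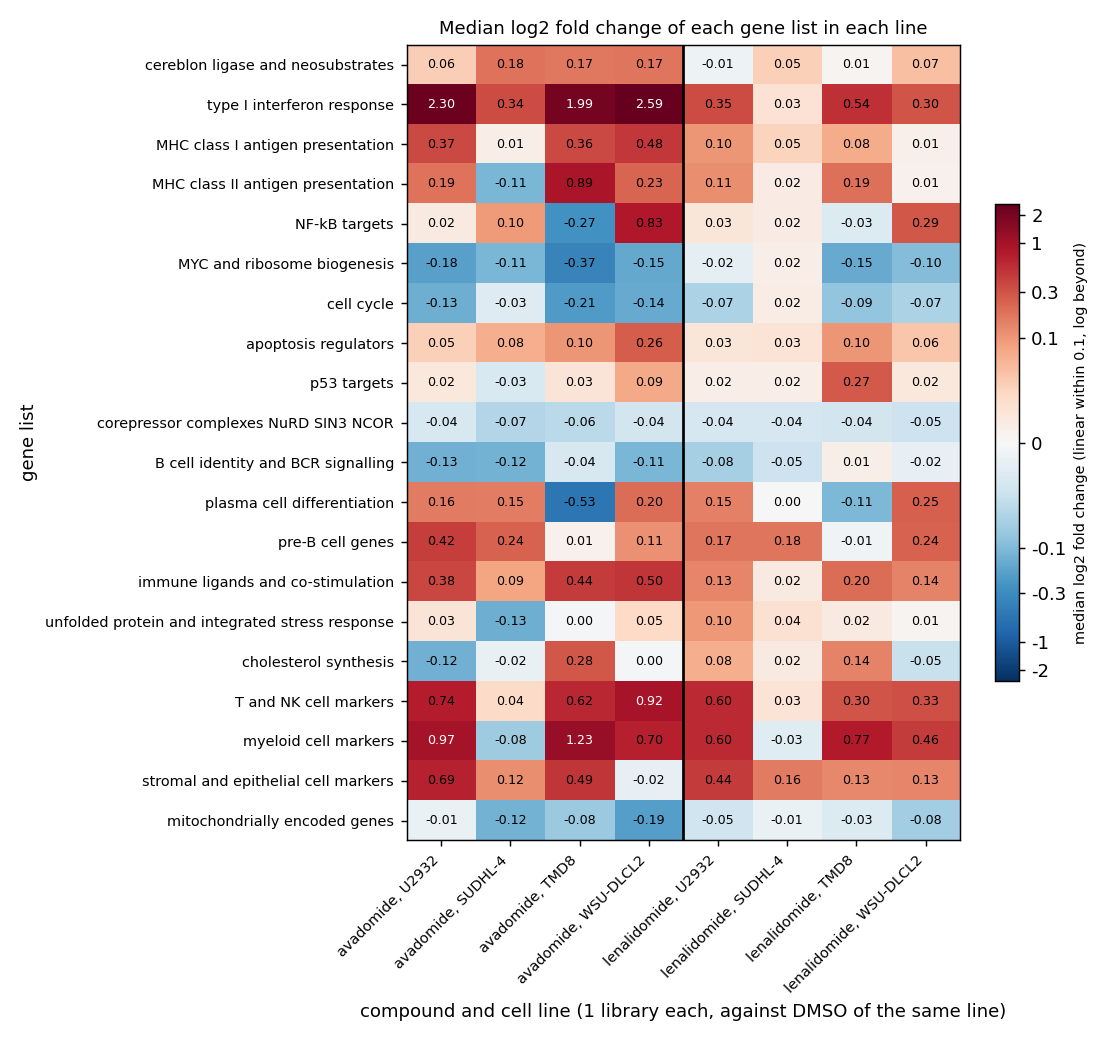
Median log2 fold change of each of 20 gene lists (y axis) in each line under avadomide and lenalidomide (x axis, 1 library each against DMSO of the same line), as colour and printed value. The colour scale is linear within 0.1 and logarithmic beyond; the interferon list has the highest values under avadomide, up to 2.59 in WSU-DLCL2.

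Lenalidomide against DMSO asked the same of the older compound. In the fit to all 12 libraries, called genes were few and nearly all higher. A fit to only the 8 libraries compared called 669, of which 512 were higher and 157 lower. That fit leaves out the spread of the avadomide libraries, which the fit to all 12 includes. NDUFC2, a subunit of respiratory complex I (chromosome 11, 78068304 to 78080219), rose by 0.73 ± 0.08 (log2, SE, n = 4; limma adjusted p = 0.0345), the cargo receptor TMED7 by 0.70 ± 0.09, the Polycomb protein BMI1 by 0.56 ± 0.07, SRP9 of the signal recognition particle by 0.54 ± 0.07 and IER3IP1 by 0.54 ± 0.07. C1orf228, ACAP2-IT1, TCTEX1D2, NRGN and BORCS7 rose by 0.81, 0.76, 0.62, 0.51 and 0.49. DOCK8, a guanine nucleotide exchange factor, fell by 0.21 ± 0.03 (adjusted p = 0.0475). NDUFC2, TMED7, BMI1 and TCTEX1D2 share exons with annotated read-through genes and ACAP2-IT1 lies in an intron of ACAP2, so their values are uncertain. In all, 53 of 22528 genes passed, 51 higher and 2 lower, and each moved the same way in 4 of 4 lines; 7 were at least 2-fold higher. At an unadjusted p under 0.05 there were 2922 genes. In the fixed lists 1 member was called, DNAJB9, at 0.33. Of the 11 genes named here, all 11 lost their call without U2932, without SUDHL-4 or without WSU-DLCL2, and 2 without TMD8. The fold change of NDUFC2 was 0.73 without U2932, 0.68 without SUDHL-4 and 0.67 without WSU-DLCL2.

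By camera, 9 lists passed under lenalidomide, 5 higher and 4 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.327. The interferon list had a median of 0.326 (camera adjusted p = 8.21e-05, and adjusted p = 0.509 with an estimated correlation) with 0 of 47 genes called, also adjusted over the list alone. Each gene was tested against the spread pooled over all 12 libraries. The interferon list missed the threshold by fry (adjusted p = 0.475). Its direction there was higher. The median of this list was 0.348 in U2932, 0.0334 in SUDHL-4, 0.543 in TMD8 and 0.295 in WSU-DLCL2. MYC and ribosome genes had a median of -0.0594 (camera adjusted p = 0.000171; 1 fell adjusted over the list alone), and the cell cycle, corepressor and mitochondrial lists lay lower by camera too, at -0.0542, -0.0449 and -0.0488. Apoptosis, p53, cereblon and myeloid lists lay higher, at 0.0742, 0.0749, 0.0202 and 0.379, the cereblon median turning to -0.0091 with the GC and length trend removed. Without TMD8 the p53 list fell to 0.036 (camera adjusted p = 0.484) and the MYC and ribosome list to -0.037 (0.0412), and the apoptosis (0.0563), cell cycle (0.191), myeloid (0.0759) and mitochondrial (0.0574) lists no longer passed. Cell cycle and myeloid lists also missed without U2932 (0.0899 each), cereblon without SUDHL-4 (0.117), and cereblon, cell cycle and mitochondrial lists without WSU-DLCL2 (0.0648 each). The cereblon median was 0.046 without U2932 or TMD8 and 0.031 without WSU-DLCL2. The call count was 0 without U2932, 1 without SUDHL-4, 0 without WSU-DLCL2, 0 with no filter and 0 without the cell line as block (61 genes at an unadjusted p under 0.05 in limma), and 669 in a fit to only the 8 libraries compared, 512 higher and 157 lower. Called genes with a transcript had a median GC content of 39.1%, against 48.7% for tested genes. Spearman correlations of fold change with GC content were -0.165 in U2932, -0.405 in SUDHL-4, 0.0373 in TMD8 and -0.376 in WSU-DLCL2, and 10 genes were called after the trend was removed, against 32 of the same genes before.

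Avadomide against lenalidomide tested the difference between the compounds directly, at doses not known to match. Interferon genes stood higher with avadomide. IFIT1 differed by 3.52 ± 0.57 (log2, SE, n = 4; limma adjusted p = 0.0177), IFIT3 by 3.35 ± 0.50, IFI44L by 3.18 ± 0.63, IFI6 by 3.06 ± 0.47 and XAF1 by 3.03 ± 0.63. Lower with avadomide were REEP2 (-1.27 ± 0.17), ATP13A4 (-1.15 ± 0.19), CELSR2 (-1.07 ± 0.14), GREB1 (-0.97 ± 0.15) and FDXACB1 (-0.84 ± 0.12). IKZF1 RNA was higher with avadomide by 0.42 ± 0.09 (adjusted p = 0.0318), IKZF2 by 0.56, XBP1 by 0.60 and CD34 by 2.73, and MYC was lower, at -0.24 ± 0.05 (adjusted p = 0.0378). No difference was shown for CRBN (-0.0016, 95% interval -0.12 to 0.12), IKZF3 (0.20, 95% interval 0.034 to 0.37; adjusted p = 0.152), IRF4 (-0.051, 95% interval -0.80 to 0.69) or IRF7 (1.53, 95% interval 0.62 to 2.43; adjusted p = 0.0612). These intervals are not adjusted over genes. Of the 12 called genes in the 6 study genes and the 10 largest changes by the naming rule, 12 lost their call without U2932. The losses were 11 without TMD8, 10 without WSU-DLCL2 and 0 without SUDHL-4. Those of IKZF1, MYC and IFIT1 were lost without U2932 (adjusted p = 0.0975, 0.155 and 0.103), without TMD8 (0.0914, 0.105 and 0.0732) and without WSU-DLCL2 (0.167, 0.174 and 0.0958), and IRF7 passed without SUDHL-4 (2.05, adjusted p = 0.00249). The log2 fold changes of IKZF1, MYC and IFIT1 were 0.40, -0.24 and 3.40 without U2932. They were 0.45, -0.25 and 3.49 without TMD8, and 0.37, -0.20 and 3.01 without WSU-DLCL2. Fewer lines also leave fewer residual degrees of freedom.

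In all, 1065 genes differed between the compounds, 565 higher and 500 lower with avadomide, each the same way in 4 of 4 lines. The split was 486 against 695 after quantile normalization. After removal of the GC and length trend, which also recentred each library, it was 312 against 516, where the same genes without the removal gave 585 against 593. Of 47 interferon genes, 29 were higher and 0 lower (46 adjusted over the list alone; median 1.55; camera adjusted p = 5.49e-26, and adjusted p = 0.340 with an estimated correlation). In the MYC and ribosome list 9 of 23 were lower (16 adjusted over the list alone; median -0.142; camera adjusted p = 1.42e-12, and adjusted p = 0.340 with an estimated correlation). In the cereblon list 6 of 14 were higher (7 adjusted over the list alone), including CUL4B (0.23) and ZFP91 (0.13). By camera 9 lists passed, 6 higher and 3 lower, with 0 left under an estimated correlation. MHC class I, MHC class II, NF-kB and immune ligand lists lay higher with avadomide (medians 0.182, 0.204, 0.196 and 0.248) and the cell cycle and mitochondrial lists lower (-0.0620 and -0.0455). Without WSU-DLCL2 the NF-kB list fell to 0.011 (camera adjusted p = 0.853) and the immune ligand list to 0.14 (0.118), MHC class I stood at 0.12 (0.0404), and MHC class II (0.114), cell cycle (0.0558) and mitochondrial (0.130) lists missed. Without TMD8 MHC class II fell to 0.045 (0.695) and immune ligands missed (0.0501), and without SUDHL-4 the cereblon (0.10) and mitochondrial (0.119) lists missed; MHC class II stood at 0.34 without SUDHL-4, and the mitochondrial list stood at -0.076 without U2932. Medians, means and tests differed in sign for the corepressor, p53, plasma cell and cholesterol lists, none of which passed. The count of genes was 0 without U2932, 507 without SUDHL-4, 62 without TMD8, 15 without WSU-DLCL2 and 0 without the cell line as block (110 genes at an unadjusted p under 0.05 in limma). Of the 29 interferon genes called, 0 were left without U2932, and 1 interferon gene was called without TMD8 or without WSU-DLCL2. The interferon list itself still passed by camera, at the preset correlation, with each line left out. Lower MYC and ribosome genes numbered 2 without SUDHL-4 and 0 without each other line, and cereblon list genes higher numbered 0, 2, 1 and 1 without U2932, SUDHL-4, TMD8 and WSU-DLCL2.

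Responses to the compounds were compared across genes, with the same DMSO libraries on each side. Of the 51 genes called higher with lenalidomide, 51 were also called higher with avadomide, and of the 2 called lower, 2 were shared; the shared DMSO libraries add to this overlap. Log2 fold changes correlated across 22528 genes at Pearson r = 0.755 and Spearman rho = 0.698, against 0.50 and 0.450 simulated with no effect and shared DMSO libraries. With the controls split by line in 6 ways, which also puts the compounds on different lines, 2 each, r averaged 0.388 (0.278 to 0.469). The covariance was 0.0689 against 0.0148 simulated, a difference of 0.0541, and 0.0479 with split controls. For interferon genes the lenalidomide change was a median of 0.199 of the avadomide change. Within single lines r was 0.736 in U2932, 0.562 in SUDHL-4, 0.701 in TMD8 and 0.641 in WSU-DLCL2. Genes are not independent replicates.

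**Figure D4:**
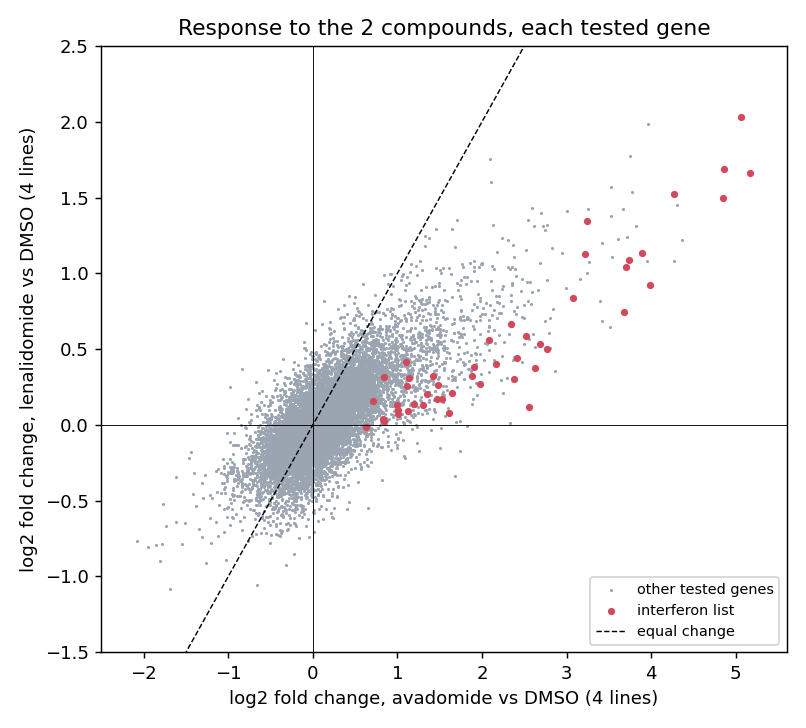
Log2 fold change against DMSO over 4 lines with avadomide (x axis) and lenalidomide (y axis) for each of 22528 genes (points), interferon list genes in red. The dashed line marks equal change; across all genes r was 0.755, and interferon genes lie below the line, with a median lenalidomide change of 0.199 of the avadomide change.

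The response of each line, read from 1 library per treatment with no test, differed in size. Under avadomide, 1646 genes were at least 2-fold changed in U2932, 2067 in TMD8 and 1681 in WSU-DLCL2, against 611 in SUDHL-4. Among the 10237 genes of at least 5 ppm the numbers higher were 190, 250 and 224, against 30 in SUDHL-4, and the numbers lower 33, 61 and 23, against 7. Under lenalidomide 565, 552 and 502 genes were at least 2-fold changed in U2932, TMD8 and WSU-DLCL2 and 295 in SUDHL-4. MHC class II genes had a median of 0.888 in TMD8 under avadomide, 0.186 in U2932, 0.233 in WSU-DLCL2 and -0.108 in SUDHL-4. MYC and ribosome genes were lowest in TMD8 (-0.37), with -0.18, -0.11 and -0.15 in U2932, SUDHL-4 and WSU-DLCL2.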

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

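Tests of noise in the shared DMSO libraries, of low values pulled together, of the CRBN level and of monocytes, T and NK cells were chosen after the results were seen, and the test of monocytes was first set for all myeloid cells and narrowed later. The other splits, the test of GC content and length and the test of whether SUDHL-4 was exposed were fixed before their results.

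Other splits of the libraries were fitted with the cell line as block. Of the 35 splits of the 8 libraries of a comparison into 4 and 4, 1, the real one, gave as many genes in each comparison, with 5582 genes for avadomide against DMSO (highest other split 0), 53 for lenalidomide against DMSO (highest other 1) and 1065 for avadomide against lenalidomide (highest other 0). The libraries are paired by line, and 8 of the splits part the libraries of all 4 lines; these are too few for a share under 0.05, and the highest of the others among them gave 0 genes in each comparison by limma. The remaining splits put the libraries of a line on the same side, where the block takes up part of the contrast, so their low counts decide nothing.

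In the fit to all 12 libraries, genes called with lenalidomide were few, low in GC content (39.1% against 48.7%) and almost all higher. Removing the trend with GC content and length left 78.6% of their median log2 fold change (0.37 before, 0.29 after), more than that trend as whole source would leave. Calls fell from 32 to 10, with 8 shared, as folds shrank and the median SE went from 0.0505 to 0.0533, so the calls themselves depend on this trend. Noise in the shared DMSO libraries alone would move both compounds alike, and 92.5% of the genes (49 of 53) lay further from DMSO with avadomide. This cannot exclude such noise. The 51 higher and 2 lower genes were also called with avadomide, and a change from avadomide added to DMSO noise would look the same. An effect of lenalidomide, noise in the shared DMSO libraries and a remaining technical trend stay open.

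Interferon genes responded least in SUDHL-4, where 10 of 47 rose at least 2-fold under avadomide. A library that never met the drug is argued against, since 89.1% of the 313 other genes changed 2-fold in the other lines (279) moved the same way in SUDHL-4. Low values pulled together are argued against too, as the 17 interferon genes at 8 or more in SUDHL-4 DMSO had a median of 0.10 there and 1.5, 1.35 and 1.77 in U2932, TMD8 and WSU-DLCL2. CRBN was lower in SUDHL-4 by a log2 difference of -0.69 (highest 10.7, lowest elsewhere 11.2), which cannot be told apart from any other property of this 1 line. A property of the line stays open, as untested.

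Some markers of other cell types rose with avadomide, 2 of 6 for T and NK cells, 3 of 6 for myeloid and 2 of 8 for stromal and epithelial cells, and none of these lists passed by camera (adjusted p = 0.124, 0.0611 and 0.456). By fry the T and NK list (adjusted p = 0.0366) and the myeloid list (0.0205) passed as higher. The stromal and epithelial list did not (0.0827). Monocytes would bring S100A8 and S100A9, whose rise was 0.316% of that of LYZ. The highest log2 value of S100A8 and S100A9 was 0, and LYZ reached a linear value of 17.3 in TMD8 with avadomide. Changes of genes with such low values are understated, so this share does not settle the question of monocytes. Other myeloid cells need not bring these genes and stay open. AIF1 (2.35), TYROBP (1.75), CX3CR1 (2.09) and F13A1 (3.16) rose at least 2-fold in each line. They were picked from these data for rising in every line, so they are no test of a cell type. The myeloid list passed by camera under lenalidomide (median 0.379, adjusted p = 0.0309, and adjusted p = 0.509 with an estimated correlation). These values do not tell added cells from a rise in the lymphoma cells themselves. For T or NK cells the test first set, the summed rise of CD3D, CD3E, CD3G and CD2 against that of NKG7, gave 25.3% and met its bar, so such cells stay open. Separate tests, added after that result, gave medians of 0.464% for CD3D, CD3E and CD3G and 0.514% for GNLY, KLRD1 and PRF1, and do not replace it. CD2 carries the sum (23.3%), rising in TMD8 from -1.36 to 4.80 beside NKG7 from 1.5 to 6.76, and its rise is unexplained.

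Single values stood apart from the other 3 lines in 8 of 175 groups of 4, where chance gives 8.8 if groups are independent and unselected. These groups share genes and DMSO libraries, and many genes were chosen for moving the same way in all 4 lines. The count therefore cannot tell whether any of these values goes beyond chance. Under avadomide these were BIRC3 in WSU-DLCL2 (1.23, others 0.52 to 0.61), XIAP in U2932 (0.31, others 0.37 to 0.38), the cereblon list median in U2932 (0.056, others 0.17 to 0.18) and the plasma cell list median in TMD8 (-0.53, others 0.15 to 0.20). Under lenalidomide they were TCTEX1D2 in TMD8 (0.24, others 0.73 to 0.77), the cell cycle list in SUDHL-4 (0.016, others -0.089 to -0.071), the p53 list in TMD8 (0.27, others 0.015 to 0.023) and the stromal and epithelial list in U2932 (0.44, others 0.13 to 0.16). IRF4 moved in opposite directions, 1.51 in WSU-DLCL2 and -1.14 in TMD8 under avadomide and 0.50 and -0.30 under lenalidomide. The difference was not tested, and the minimum size of 0.25 behind this choice was lowered from 0.5 after no gene met the larger one.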

How the results depend on the processing

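Removal of the GC and length trend, and the fit to genes with a matched transcript that goes with it, were chosen after the data were seen; the other alternatives were planned. Planned runs with other pseudocounts and with count-based tools were not run, since the deposited values are log2. The stricter filter left 19 of the 20 lists with a value. Unless given, the cause was not tested.

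Without the cell line as block, limma called 0 genes in each comparison (514, 61 and 110 at an unadjusted p under 0.05 for avadomide, lenalidomide and avadomide against lenalidomide), because differences between lines then count as noise, and 4 lists passed for lenalidomide in place of 9. Leaving out 1 line gave 2666 (WSU-DLCL2) to 4644 (SUDHL-4) genes for avadomide, 0 (U2932, WSU-DLCL2) to 67 (TMD8) for lenalidomide and 0 (U2932) to 507 (SUDHL-4) for avadomide against lenalidomide; for the zeros, 1849 and 1904 genes for lenalidomide and 3918 for avadomide against lenalidomide had an unadjusted p under 0.05. Leaving out a line also leaves fewer residual degrees of freedom, so a lost call need not mean a smaller change. Lists past the threshold ranged from 6 to 10, 5 to 9 and 4 to 10. Fitting only the 8 libraries compared gave 1376 genes for avadomide, and 669 genes and 15 lists for lenalidomide.

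With no filter, 0 genes were called for lenalidomide (3609 at an unadjusted p under 0.05), 220 for avadomide against lenalidomide, and 14 lists passed for avadomide in place of 7. The stricter filter gave 132 genes for lenalidomide (48 shared with the 53) and 4 lists. Quantile normalization gave 18 genes for lenalidomide, the genes with a matched transcript 32, and removal of the GC and length trend 10. Quantile normalization moved the median of all genes under avadomide to -0.063.

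With an estimated correlation between genes, 0 lists passed in each comparison. By fry, 12, 2 and 3 lists passed, with smallest adjusted p of 0.000545, 0.0211 and 0.00696. Under avadomide the apoptosis, corepressor, B cell, pre-B, immune ligand, T and NK and myeloid lists passed by fry and missed by camera. The NF-kB and cell cycle lists passed by camera and missed by fry (adjusted p = 0.169 and 0.0576). Under lenalidomide the lists that passed by fry were cereblon (adjusted p = 0.0462) and corepressor (0.0211). With the estimated correlation, the interferon medians of 1.98, 0.33 and 1.55 had camera adjusted p of 0.358, 0.509 and 0.340. This is a consequence of the larger correlation, estimated at 0.735 for this list against the preset 0.01. Without 1 line the medians ranged over 1.64 to 2.62, 0.26 to 0.39 and 1.23 to 2.05, all past the threshold with the preset correlation. The correlation of the compounds was 0.388 with split controls, where the compounds share no DMSO library but are also measured on different and fewer lines. It was 0.839 for genes of at least 5 ppm. No chance value was simulated for those genes, so this cannot be read as closer agreement.

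Medians reversed in 4 cases with a call before or after, in 3 lists. The cereblon list went to -0.0084 under avadomide and -0.0091 under lenalidomide with the GC and length trend removed. The plasma cell list under lenalidomide ran from -0.0078 (without U2932) to 0.069 (without TMD8), and the cholesterol list for avadomide against lenalidomide from -0.047 (without TMD8) to 0.038 (without U2932). Of 717 alternatives for list medians, 597 kept their side of the threshold, 20 of these with a change of sign in a median that did not pass, 77 lost and 39 gained a pass. Of 1474 for named genes, 1127 kept their side of the threshold, 12 of these with a change of sign in a gene that did not pass, 336 lost and 11 gained a pass, and 0 called genes reversed. Depth is unknown; the spread at low values limits genes with means under 5.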

Other observations

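The gene families, the genes changed in every line and the test on SUDHL-4 here were chosen after the data were seen.

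In all, 92 genes were called with avadomide and at least 2-fold higher in each of the 4 lines, 10 of them in the interferon list, and 6 were lower. Among the higher were PTGIR, the prostacyclin receptor (3.67), SLC12A3, a sodium chloride transporter (3.24), the clotting factor subunit F13A1 (3.16), LAMP3 (2.41), RAB13 (2.36), AIF1 (2.35), the chemokine receptor CX3CR1 (2.09) and the adaptor TYROBP (1.75). IFNB1, which encodes interferon beta, rose by 1.89 ± 0.39 (log2, SE, n = 4 lines; limma adjusted p = 0.00734), with 1.99 in U2932, 0.25 in SUDHL-4, 3.12 in TMD8 and 2.20 in WSU-DLCL2.

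Of 16 gene families tested, interleukin receptors, integrins, S100 proteins, histones and ZNF genes did not pass by camera for avadomide against DMSO (adjusted p from 0.10 to 0.572). The other families passed there, and with an estimated correlation the smallest adjusted p of any family was 0.406. Under lenalidomide only TNF superfamily ligands passed by camera (adjusted p = 0.00831). For avadomide against lenalidomide S100 proteins passed too (camera adjusted p = 0.0428), and the smallest adjusted p with an estimated correlation was 0.313. Of 77 mitochondrial ribosomal protein genes, 34 fell and 1 rose with avadomide (median -0.12; camera adjusted p = 1.01e-10, and adjusted p = 0.406 with an estimated correlation), and the median stayed negative after quantile normalization (-0.145) and removal of the GC and length trend (-0.137). Of 12 TNF superfamily ligands, 8 rose and 0 fell (median 0.60, with 0.56 and 0.60 under those alternatives; camera adjusted p = 0.000642, and adjusted p = 0.406 with an estimated correlation), among them TNFSF15 (3.01), the B cell survival factor TNFSF13B (2.32) and TNFSF13 (1.13). Of 5 guanylate-binding proteins 2 rose, with GBP4 at 3.78, of 6 APOBEC3 genes 3, with APOBEC3H at 1.55, and of 9 Toll-like receptors 4 (2 after removal of the GC and length trend), with TLR3 and TLR7 at 1.90 and 1.71. These 3 families each had an adjusted p of 0.406 with an estimated correlation. Some of these genes are also in the fixed lists.

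A weaker response of SUDHL-4 to avadomide may hold for all raised genes alike and not for interferon genes alone. The 43 interferon genes raised 2-fold in the other lines reached 17.6% of that size in SUDHL-4, against a median of 24.3% for 10000 random matched sets of the 744 other raised genes (middle 95% from 14.6 to 36.3). The interferon genes stood at percentile 6.63 of these sets, so the test did not set them apart. The other genes were all raised genes outside the fixed list, so interferon-induced genes missing from that list were not removed. Such genes would draw the sets towards the interferon genes, and matching on size of rise and level was coarse. Whether the weaker response is alike for all raised genes is therefore not decided. The smallest group drawn from held 7 genes.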
